A study of Homo sapiens with 6 samples.

How the data were processed

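The data were RNA sequencing libraries of BJ fibroblasts, 2 for each of 3 days (0, 2 and 5). Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into libraries with an Illumina TruSeq RNA kit. The deposited values were expected counts per gene, estimated counts that need not be whole numbers and that were not scaled between samples, per the file headers and the values themselves. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting were not given in the sources used here. The deposited table also held a mean expected count per day, which was not used. How multiply mapped reads were shared decides the counts of near-identical genes, so values of ribosomal protein genes, which have many pseudogenes, and of other paralogs are uncertain to that extent. Since the strand setting was not given, reads of overlapping and antisense genes cannot be told apart.

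The table held 60843 genes. Of these, 172 had no gene name and were left out of library sizes and tests, with 0.0356 to 0.0475% of the counts of a library. Of all values, 87.2% were exactly whole, and the rest were rounded to whole numbers before testing. For 76 symbols given to more than 1 gene, the gene with the highest mean count was used under that symbol. Library totals ran from 17605858 to 27953926 counts. The day 5 libraries were the shallowest, so low levels were least certain there. A floor of 3 counts was used for genes with no counts, summed over both libraries of a day for fold changes and per library for detection limits. Ratios for genes with 1 to 3 counts in a group carry exact 95% intervals conditional on the total count. Levels are CPM scaled by TMM factors.

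Groups came from the time point in the labels. All 6 libraries entered 1 fit by group in edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr at its minimum count of 10 and minimum total count of 15, and the quasi-likelihood test at 3 residual degrees of freedom. This left 16327 genes. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Changes above 2-fold were tested with glmTreat at a log2 fold change of 1. All p-values are two-sided, except those of the annotation terms, which were tested for enrichment only and are one-sided.

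The 31 gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the first set of other settings. They cover fibroblast and neuronal identity, markers of other cell types, and signalling, stress, metabolic and cell cycle genes. The 27 lists with at least 5 tested members were tested with camera in limma 3.58.1, on log-CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists of a comparison. Camera was run again with the correlation estimated from the data, for which the test has 3 degrees of freedom. Under that setting 0 lists were called in each comparison, and 7, 9 and 5 lists had an unadjusted p under 0.05. The directional test fry, which asks whether the genes of a set move one way on balance and compares them with no other genes, called 27, 26 and 27 lists.

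Genes were named by rule. In each comparison the rule took the 8 largest log2 fold changes in each direction among called genes with a mean of at least 5 CPM, both libraries of a day above both of the other, and a symbol that was not a clone, LOC or antisense name. It also took up to 4 members of lowest adjusted p from each called list and always from the fibroblast, pan-neuronal, neurogenic, cAMP and cell cycle lists. TUBB3, MAP2, RBFOX3, DCX, NEUROD1, NEUROG2, COL1A1, VIM, CREM, NR4A1 and MKI67 were named whatever their result. The results of some genes that the rule takes are not reported here. Coordinates came from GENCODE release 29 on GRCh38, matched by gene identifier for 159 of 159 named genes. Annotation terms in the deposited table, 4092 terms of 10 to 500 tested genes, were tested with Fisher's exact test against the 15094 tested genes with a term. Overlaps of calls between comparisons that share libraries were set beside 20 simulated draws with no change.

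The other settings fixed at that time were DESeq2 1.42.0, limma-voom, RLE size factors, no count filter, a stricter filter (CPM of at least 1 in at least 4 libraries), fits of only the groups compared, the replicate number as a block, glmTreat and leaving out each library. Chosen after seeing the data were library totals without TMM factors, leaving out IGFBP5, terms from glmTreat calls and an assumed variation of at least 20% in every gene. The edgeR steps were tested on simulated data with 200 changed genes. For day 2 against day 0 (15405 genes) 67.7, 87.1 and 98.5% of genes changed 1.5, 2 and 4-fold were recovered, with 25 false calls. For day 5 against day 0 (15406 genes) the shares were 71.8, 87.0 and 97.3%, with 10 false calls, and for day 5 against day 2 (15355 genes) 71.9, 89.7 and 98.5%, with 14 false calls. In a separate simulation for each comparison, camera called a list of 15 genes raised 1.5 times. It also called 4% of the other lists for day 2 against day 0, and 0% in the other comparisons.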

Results

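RNA sequencing was analysed for 6 libraries of BJ cells, an established line of normal human foreskin fibroblasts. The cells were collected at day 0, day 2 and day 5 of a chemical protocol, with 2 libraries per day. By its title, the series concerns the chemical reprogramming of these fibroblasts into cells named FiNs. Day 0 cells had grown in medium with serum. They were then moved to neuronal induction medium with 10 µM forskolin, and at day 2 to neuronal maturation medium with forskolin. Forskolin is a plant diterpene that activates adenylyl cyclase and so raises cAMP. Cells in the new media without forskolin were not analysed here, so time, medium and drug changed together after day 0.

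The libraries held 23121143 and 26701024 expected counts at day 0, 24955882 and 27953926 at day 2, and 17605858 and 19313704 at day 5. At these depths 3 counts corresponded to 0.118 and 0.103 CPM (counts scaled to a common library size) at day 0, 0.125 and 0.112 CPM at day 2, and 0.180 and 0.164 CPM at day 5. Levels are given as mean ± SD of CPM over the 2 libraries of a day, and log2 fold changes as value ± standard error (SE). Adjusted p-values of single genes come from the edgeR quasi-likelihood test, with Benjamini-Hochberg adjustment over 16327 genes. The labels do not say whether the libraries of a day came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Floors and counting intervals cover counting error only.

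The days differed in many genes. The first principal component held 63.5% of the variance and ordered the libraries by day, and the second held 27.6% and set day 2 apart from both other days. Between day 0 and day 2, 5457 genes rose and 5455 fell, or 66.8% of those tested. Between day 0 and day 5, 5839 rose and 5566 fell (69.9%), and between day 2 and day 5, 5241 rose and 5505 fell (65.8%). The replicate libraries lay close together, with a common coefficient of biological variation of 3.33%, so many small changes passed the test. Changes larger than 2-fold, tested as such with glmTreat, numbered 1141 higher and 904 lower at day 2 against day 0, 1591 and 1687 at day 5 against day 0, and 1046 and 1299 at day 5 against day 2. Scaling by library totals alone moved the median gene by -0.18 log2 at day 2 and -0.21 at day 5 against day 0. Under that scaling 4249 genes were higher and 6902 lower at day 2, or 38.1% of calls higher against 50.01% with TMM scaling. At day 5 they were 4415 and 6899, or 39.0% against 51.2%. All changes given here are relative to the TMM scaling.

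**Figure D1:**
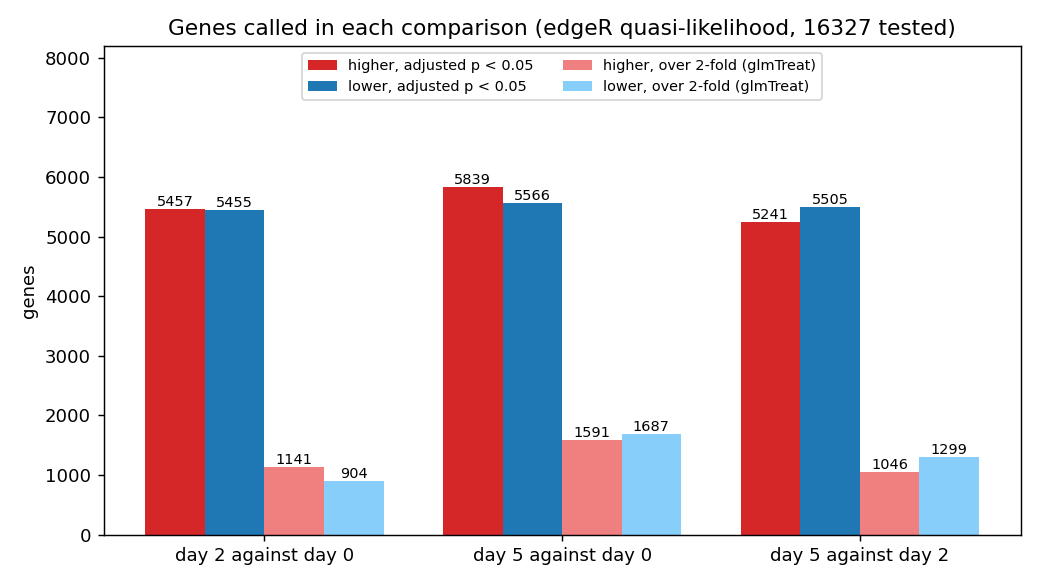
Number of genes (y axis, from 0) called higher or lower in each of the 3 comparisons (x axis), with bars for all calls at an adjusted p under 0.05 by edgeR and for calls of a change over 2-fold by glmTreat. At day 5 against day 0, 5839 genes were higher and 5566 lower, of which 1591 and 1687 passed the 2-fold test.

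The most abundant genes took a larger part of the libraries on later days. IGFBP5, an insulin-like growth factor binding protein, held 0.380% and 0.378% of the counts at day 0, 0.355% in both day 2 libraries and 10.7% in both day 5 libraries. The 10 most abundant genes together held 6.59% of each day 0 library, 10.3% of each day 2 library and 20.8% of each day 5 library. TFPI2, a secreted protease inhibitor, went from 0.0208% at day 0 to 1.69% and 1.66% at day 2 and 1.06% and 1.04% at day 5. Among the genes followed at every day, TUBB3 (ENSG00000258947) lies on chromosome 16 at 89921392 to 89938761 of GRCh38, MAP2 (ENSG00000078018) on chromosome 2 at 209424058 to 209734118, and COL1A1 (ENSG00000108821) on chromosome 17 at 50183289 to 50201632. VIM (ENSG00000026025) lies on chromosome 10 at 17228259 to 17237593, CREM (ENSG00000095794) on chromosome 10 at 35126791 to 35212958, NR4A1 (ENSG00000123358) on chromosome 12 at 52022832 to 52059507, and MKI67 (ENSG00000148773) on chromosome 10 at 128096659 to 128126385. All are annotated as protein-coding, and the values are per gene.

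Day 2 was compared with day 0 to find what changed over the first 2 days in induction medium with forskolin. IL1B, which encodes a proinflammatory cytokine, rose from 0.258 ± 0.0251 to 314 ± 1.55 CPM, and MX1, an interferon-induced antiviral GTPase, fell from 496 ± 11.4 to 10.6 ± 0.0111 CPM. STC1, a member of the cAMP and CREB target list, went from 114 ± 0.571 to 2287 ± 16.6 CPM. Both TUBB3 and MAP2 fell. MKI67, a marker of dividing cells, fell from 14.8 ± 1.03 to 0.623 ± 0.355 CPM.

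Of 31 tested cAMP and CREB targets, 23 rose and 1 fell at day 2, with a median log2 fold change of 1.30 (camera adjusted p = 2.7e-06, adjusted p = 0.0617 with an estimated correlation). STC1, a secreted glycoprotein hormone, rose by 4.33 ± 0.02 on the log2 scale. PDK4, a kinase that inhibits pyruvate dehydrogenase, rose 39.1-fold to 2659 ± 19.99 CPM. PTGS2, the inducible cyclooxygenase, rose by 4.56 ± 0.04 log2, and AREG, a ligand of the EGF receptor, by 4.22 ± 0.04. The orphan nuclear receptor NR4A1 went from 7.78 ± 1.33 to 48.5 ± 2.17 CPM (log2 fold change 2.65 ± 0.08, edgeR adjusted p = 1.8e-14). CREM, the cAMP-responsive modulator, changed little, from 15.4 to 17.7 CPM (log2 fold change 0.20 ± 0.08, edgeR adjusted p = 0.043). That CREM call was lost with DESeq2 (adjusted p = 0.134), with RLE factors (adjusted p = 0.0618), without TMM factors (adjusted p = 0.891) and when any 1 of the 4 libraries was left out, with adjusted p from 0.0411 to 0.891 over all alternatives.

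Inflammatory and matrix protease genes moved the same way, with 19 of 22 higher and 2 lower (median 1.85, camera adjusted p = 1.8e-06, adjusted p = 0.0617 with an estimated correlation). Among the genes named by rule, IL1B showed the largest rise, a log2 fold change of 10.23 ± 0.09 (edgeR adjusted p = 3.3e-22). It lies on chromosome 2 at 112829751 to 112836903, near IL1A at 112773915 to 112784590, which rose by 6.14 ± 0.22. The neutrophil chemoattractant CXCL8 went from 35.0 to 255 CPM and the collagenase MMP1 from 415 to 1651 CPM. Other large rises were those of G0S2, an inhibitor of lipolysis (393-fold), the cytokine IL24 (156-fold), the matrix glycoprotein THBS2 (107-fold, to 704 ± 6.99 CPM) and TFPI2 (91.5-fold, to 17409 ± 188 CPM, edgeR adjusted p = 9.0e-30).

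All 22 tested interferon-stimulated genes fell at day 2, with a median log2 fold change of -3.53 (camera adjusted p = 2.8e-11, adjusted p = 0.0617 with an estimated correlation). OAS1, a sensor of double-stranded RNA, was 111-fold lower, and its neighbours on chromosome 12, OAS3 and OAS2, had log2 fold changes of -5.57 ± 0.09 and -6.12 ± 0.12. MX1 was 46.7-fold lower (log2 fold change -5.55 ± 0.04, edgeR adjusted p = 2.3e-22). IFI6 went from 807 to 75.2 CPM and the ubiquitin-like modifier ISG15 from 527 to 63.7 CPM.

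Of 39 tested cell cycle genes, 34 fell and 2 rose (median -1.73, camera adjusted p = 2.5e-08, adjusted p = 0.0617 with an estimated correlation). MKI67 was 24.0-fold lower (log2 fold change -4.59 ± 0.23, edgeR adjusted p = 1.3e-11), and the mitotic cyclin CCNB1 went from 26.0 to 4.24 CPM. In the p53 and senescence list 14 of 21 rose and 6 fell (median 0.88, camera adjusted p = 0.036, adjusted p = 0.237 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A went from 1505 to 3643 CPM, and CDKN1C, an inhibitor of the same class, from 5.20 to 26.8 CPM. Contractile genes fell in 17 of 18 cases and rose in 1 (median -0.84, camera adjusted p = 1.8e-06, adjusted p = 0.0617 with an estimated correlation). Among them, the actin-binding protein TAGLN went from 799.8 ± 14.5 to 197 ± 6.55 CPM.

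Ribosomal protein genes rose in 36 of 36 cases, with a median of 0.69 (camera adjusted p = 7.2e-12, adjusted p = 0.131 with an estimated correlation). RPL3, for example, went from 1001 to 1970.3 CPM. The list of the integrated stress and unfolded protein responses had 16 of 23 members higher and 5 lower (17 and 5 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.0053, adjusted p = 0.153 with an estimated correlation). Its endoplasmic reticulum chaperones HSP90B1 and HSPA5 went from 394 to 1342 CPM and from 609 to 1235 CPM. Mitochondrially encoded mRNAs fell in 10 of 13 cases and rose in 1 (median -0.43, camera adjusted p = 0.0042, adjusted p = 0.576 with an estimated correlation). Mitochondrial ribosomal RNA moved the other way, from 0.436% and 0.423% of counts at day 0 to 1.22% and 1.18% at day 2. Voltage-gated ion channels fell in 12 of 22 cases and rose in 1 (median -0.63, camera adjusted p = 0.045, adjusted p = 0.293 with an estimated correlation). KCND3, a potassium channel, had a log2 fold change of -4.49 ± 0.28, and the sodium channel SCN9A went from 68.0 to 38.8 CPM. This call was lost with RLE scaling (camera adjusted p = 0.0505), with library totals (0.0953), without day 0 replicate 1 (0.0698) and without day 2 replicate 2 (0.0604), with camera adjusted p from 0.0266 to 0.293 over all alternatives.

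The fibroblast identity and matrix list was split at day 2, with 18 of 30 genes higher and 10 lower (camera adjusted p = 0.26), or 14 and 14 with library totals. COL1A1, a chain of type I collagen, fell from 4284 ± 111 to 1076 ± 41.4 CPM (log2 fold change -1.99 ± 0.02, edgeR adjusted p = 2.5e-20). The proteoglycan DCN also fell, from 1044 to 269 CPM, while LOX, which crosslinks collagen, went from 151 to 440.4 CPM. The intermediate filament gene VIM stayed near 4851 ± 8.53 CPM, at 5044 ± 8.24 CPM. Its log2 fold change was 0.06 ± 0.01 with TMM scaling and -0.13 with library totals, which reversed the call, so no direction could be given for it. Of the alternatives for VIM, the log2 fold change ranged from -0.13 to 0.06.

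Of 31 pan-neuronal genes, only 15 had enough counts to be tested. They were not called as a list at day 2, where 3 of these 15 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.13). TUBB3, a tubulin of neurons, fell from 226 ± 4.26 to 139.8 ± 4.46 CPM (log2 fold change -0.69 ± 0.03, edgeR adjusted p = 8.7e-12). MAP2, a microtubule-associated protein of dendrites, fell from 12.96 ± 1.70 to 4.44 ± 0.620 CPM (log2 fold change -1.54 ± 0.20, edgeR adjusted p = 2.9e-06). SCG2, a granin of secretory vesicles, rose from 1.09 ± 0.184 to 9.42 ± 0.111 CPM. Of 34 neurogenic transcription factors only SOX4, SOX11 and DLX1 had enough counts to be tested, and the 3 were called higher. SOX4 went from 97.4 ± 2.18 to 199.6 ± 3.33 CPM and SOX11 from 9.69 to 12.2 CPM. DLX1 had 1 count over both day 0 libraries and 13 at day 2, a ratio of 13.9 with a 95% counting interval of 2.09 to 591. The SOX11 call was lost with library totals (edgeR adjusted p = 0.261) and without day 0 replicate 2 (0.147) or day 2 replicate 1 (0.128), over a range of 0.0143 to 0.261. The DLX1 call was lost without day 0 replicate 2 (edgeR adjusted p = 0.0821), over a range of 0.0105 to 0.0821.

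The proneural factors NEUROD1 and NEUROG2 were not detected, or nearly not, on any day. NEUROD1 (chromosome 2 at 181673088 to 181680876) had 0 counts in all 6 libraries. NEUROG2 (chromosome 4 at 112513516 to 112516172) had 1 count, in day 0 replicate 2. DCX, a microtubule protein of young neurons, had 1 count in day 2 replicate 1 and 1 in day 5 replicate 2. RBFOX3, which encodes the nuclear antigen NeuN, had 3 and 5 counts at day 0, 8 and 14 at day 2, and 6 and 8 at day 5, too few to be tested. At day 5 a gene with 0 counts could have been present at up to 0.180 CPM in the shallower library.

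Day 5 was compared with day 0 to find how far the cells had moved from the starting fibroblasts after both media with forskolin. The receptor gene PDGFRA, a marker of mesenchymal cells, rose from 334 ± 9.22 to 2641 ± 45.0 CPM, while TAGLN fell 143-fold to 5.58 ± 0.0875 CPM. TUBB3 fell further, to 87.4 ± 0.335 CPM, and MAP2 to 0.835 ± 0.672 CPM. NR4A1 rose to 199 ± 6.07 CPM, and MX1 fell to 1.28 ± 0.0359 CPM. SSTR2, a somatostatin receptor coupled to G proteins, rose from 0.462 to 568 ± 10.5 CPM.

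Of the cAMP and CREB targets, 26 of 31 rose and 5 fell at day 5 (median 1.97, camera adjusted p = 4.3e-06, adjusted p = 0.0794 with an estimated correlation). NR4A1 was 25.8-fold higher than at day 0 (log2 fold change 4.69 ± 0.07, edgeR adjusted p = 5.1e-19), and its relative NR4A2 went from 13.9 to 242 CPM. AREG was 61.0-fold higher, at 879 ± 0.581 CPM. The cAMP phosphodiesterase PDE3A was 453-fold higher, at 119 CPM. CREM went from 15.4 to 41.5 CPM (log2 fold change 1.43 ± 0.08, edgeR adjusted p = 3.0e-11). STC1 reached 2450.1 ± 24.6 CPM.

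Interferon-stimulated genes fell in 22 of 22 cases, with a median of -5.19 (camera adjusted p = 5.4e-11, adjusted p = 0.0794 with an estimated correlation). MX1 was 384-fold lower (log2 fold change -8.58 ± 0.07), and IFI6 went from 807 ± 1.71 to 12.7 CPM. OAS2 had no counts at day 5 and was at least 896-fold lower, with the floor set at 3 counts over both libraries of a day.

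Contractile genes fell in 17 of 18 cases and rose in 1 (median -1.46, camera adjusted p = 9.6e-08, adjusted p = 0.0794 with an estimated correlation). TAGLN had a log2 fold change of -7.16 ± 0.05 (edgeR adjusted p = 2.0e-23), the myosin light chain MYL9 went from 824 to 45.9 CPM, and the myosin kinase MYLK from 1622 to 223 CPM. YAP and SRF targets fell in 12 of 16 cases and rose in 4 (median -1.85, camera adjusted p = 0.0029, adjusted p = 0.203 with an estimated correlation). Here CCN1, a matricellular protein, went from 345 to 23.7 CPM and tissue factor, F3, from 1393 to 83.0 CPM. Its relative CCN2 rose, from 436 to 1316 CPM. Cell cycle genes fell in 36 of 39 cases and rose in 1 (median -1.08, camera adjusted p = 1.6e-06, adjusted p = 0.0794 with an estimated correlation). MKI67 was lower than at day 0 by a smaller margin than at day 2, with a log2 fold change of -1.23 ± 0.17 (edgeR adjusted p = 4.7e-06).

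Several metabolic lists fell. Glycolysis and hypoxia genes were lower in 19 of 24 cases and higher in 3 (median -0.65, camera adjusted p = 0.00012, adjusted p = 0.105 with an estimated correlation). The pyruvate kinase PKM went from 3174 to 1019 CPM, while the angiogenic factor VEGFA of the same list rose from 47.3 to 376 CPM. Oxidative stress genes were lower in 12 of 16 cases and higher in 3 (median -1.31, camera adjusted p = 0.00093, adjusted p = 0.105 with an estimated correlation). TXNRD1, a thioredoxin reductase, went from 1279.6 to 181 CPM and the quinone reductase NQO1 from 838 to 189 CPM. Sterol synthesis genes were lower in 17 of 23 cases and higher in 3 (median -0.45, camera adjusted p = 0.0022, adjusted p = 0.105 with an estimated correlation), among them FDPS with a log2 fold change of -1.06.

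Ribosomal protein genes were higher than at day 0 in 34 of 36 cases and lower in 0 (median 0.48, camera adjusted p = 8.7e-08, adjusted p = 0.141 with an estimated correlation). Mitochondrially encoded mRNAs rose in 13 of 13 cases (median 0.54, camera adjusted p = 0.00033, adjusted p = 0.439 with an estimated correlation). MT-CO1 went from 12231 to 20316 CPM, and mitochondrial ribosomal RNA held 0.576% and 0.561% of counts at day 5. The stress response list had 18 of 23 members higher and 2 lower (median 0.82, camera adjusted p = 0.0018, adjusted p = 0.105 with an estimated correlation), among them DDIT4 with a log2 fold change of 2.29 ± 0.06. Inflammatory genes were higher in 15 of 22 cases and lower in 4 (median 1.29, camera adjusted p = 0.0022, adjusted p = 0.105 with an estimated correlation). The cytokine LIF went from 155 to 987 CPM and IL11 from 10.3 to 131 CPM. BMP, WNT and NOTCH targets rose in 12 of 16 cases and fell in 4 (median 1.57, camera adjusted p = 0.013, adjusted p = 0.150 with an estimated correlation). The transcriptional repressor HEY1, a NOTCH target, was 121-fold higher, and ID3, a BMP target, went from 104 to 418 CPM.

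The fibroblast list was not called at day 5, with 18 of 30 genes higher and 12 lower (camera adjusted p = 0.11). COL1A1 was close to its day 0 level, at 3725 ± 69.7 CPM (log2 fold change -0.20 ± 0.02, edgeR adjusted p = 3.3e-07). PDGFRA was 7.91-fold higher (log2 fold change 2.98 ± 0.02, edgeR adjusted p = 3.4e-23). The type VI collagen chain COL6A3 went from 5672 to 13587 CPM and the matrix protein FBLN1 from 195 to 1237 CPM. VIM fell from 4851 to 1466 ± 11.4 CPM (log2 fold change -1.73 ± 0.01, edgeR adjusted p = 6.9e-23). Of 16 TGF-beta targets 7 rose and 9 fell (camera adjusted p = 0.67).

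Pan-neuronal genes were mixed at day 5, with 5 of the 15 tested higher and 8 lower (camera adjusted p = 0.39). Their most abundant member, the neuronal ubiquitin hydrolase UCHL1, went from 974 ± 6.09 to 211 ± 3.75 CPM. TUBB3 was 2.59-fold lower (log2 fold change -1.37 ± 0.04, edgeR adjusted p = 1.6e-15), and MAP2 was 15.1-fold lower (log2 fold change -3.92 ± 0.28, edgeR adjusted p = 1.4e-09). Members that rose included SCG2, CHGB, STMN3 and CRMP1. SCG2 was 31.0-fold higher, at 33.8 ± 3.17 CPM (edgeR adjusted p = 7.6e-15). CHGB, a second granin, went from 0.216 to 8.34 CPM. CHGB and CRMP1 were picked out after their values were seen, as were the members named of the subtype, melanocyte and pluripotency lists. SOX4, SOX11 and DLX1 were again higher, with SOX4 at 419 ± 2.42 CPM and DLX1 at a ratio of 82.5 with a counting interval of 14.2 to 3318.

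Other neuronal lists were not called at day 5, and part of their members had too few counts to be tested. The tested genes were 20 of 30 synaptic, 9 of 31 receptor, 22 of 33 channel and 27 of 34 axon guidance genes. Of 20 synaptic genes 6 rose and 3 fell (camera adjusted p = 0.86), of 9 neurotransmitter receptors 5 rose and 3 fell (camera adjusted p = 0.29), and of 27 axon guidance genes 16 rose and 8 fell (camera adjusted p = 0.14). Voltage-gated channels fell in 12 of 22 cases and rose in 5 (camera adjusted p = 0.051), and were called lower with the replicate block (0.0453) and without day 0 replicate 2 (0.0486), day 5 replicate 1 (0.0211) or day 5 replicate 2 (0.0211). With library totals the axon guidance genes were called higher (0.0341). Only 2 of 31 neurotransmitter subtype genes were tested, and CALB2 fell while GAD1 was not called. Markers of other lineages were mixed too, and many were not tested for lack of counts. Tested were 13 of 25 glial, 7 of 18 keratinocyte, 8 of 20 endothelial and immune and 5 of 18 muscle, cartilage and bone genes. Of 13 glial and neural crest genes 6 rose and 5 fell (camera adjusted p = 0.93), of 7 keratinocyte genes 1 rose and 5 fell (0.14), of 8 endothelial and immune genes 2 rose and 4 fell (0.52), and of 5 muscle, cartilage and bone genes 1 rose and 1 fell (0.85). In the melanocyte list KIT and PMEL rose and MITF fell, of 4 tested. In the pluripotency list DNMT3B fell, of 2 tested, and neither gene was called when adjusted over the list alone. Genes of fatty acid metabolism (9 higher and 8 lower of 19, camera adjusted p = 0.85) and of oxidative phosphorylation (14 higher and 7 lower of 27, 14 and 8 adjusted over the list alone, camera adjusted p = 0.29) were not called. With library totals the splits were 6 higher and 12 lower for oxidative phosphorylation, 7 and 9 for fatty acid metabolism, 5 and 5 for the synaptic genes and 4 and 5 for the glial genes. The p53 list was not called either (14 higher and 5 lower of 21, camera adjusted p = 0.069).

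For several uncalled lists the median, the mean and the test differed in sign at day 5. The pan-neuronal list had a median of -0.63, a mean of 0.13 and a test direction of lower, and the TGF-beta list a median of -0.38, a mean of 0.17 and the direction lower. The synaptic list had a median of -0.06 with a mean of 0.14 and the direction higher, the endothelial list -0.98 with 0.17 and lower, and the muscle list 0.20 with -0.24 and higher. At day 2 against day 0, median, mean and test direction differed for the glial list (-0.30, 0.54, lower), the keratinocyte list (0.08, -0.10, higher) and the muscle list (0.48, -0.07, higher). Between day 2 and day 5 they differed for the receptors (-0.87, 0.44, lower), the pan-neuronal genes (-0.19, 0.30, lower), the stress response genes (0.15, -0.09, higher) and the muscle list (0.31, -0.17, higher). They also differed there for the synaptic (-0.02, 0.08, lower), p53 (-0.0084, 0.14, lower) and oxidative phosphorylation genes (-0.02, 0.06, higher). Apart from the lists where other counts are given, and 12 higher and 10 lower of 27 oxidative phosphorylation genes (12 and 9 over all genes) and 6 and 5 of 13 glial genes (5 and 5) at day 2, counts adjusted over the list alone were the same as over all genes. With library totals the day 2 splits were 8 higher and 15 lower for oxidative phosphorylation and 3 and 5 for the glial genes.

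Other large changes at day 5 included genes outside these lists. SMOC1, a secreted calcium-binding protein, had 3 counts at day 0 and reached 455 ± 2.82 CPM, a ratio of 8256 with a counting interval of 2824 to 40036. SSTR2 was 1177-fold higher (log2 fold change 10.20 ± 0.10), the aggrecanase ADAMTS4 743-fold and the matrix protein ABI3BP 472-fold. The growth factor BMP6 had 1 count at day 0 and a ratio of 896 with a counting interval of 160 to 35462. Among the genes that fell, CLDN1, a tight junction protein, had 1 count at day 5 and a ratio of 2725 with a counting interval of 489 to 107649. LRRC15 was at least 313-fold lower, CALB2, a calcium-binding protein, at least 221-fold and the carboxypeptidase CPA4 at least 191-fold.

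**Figure D2:**
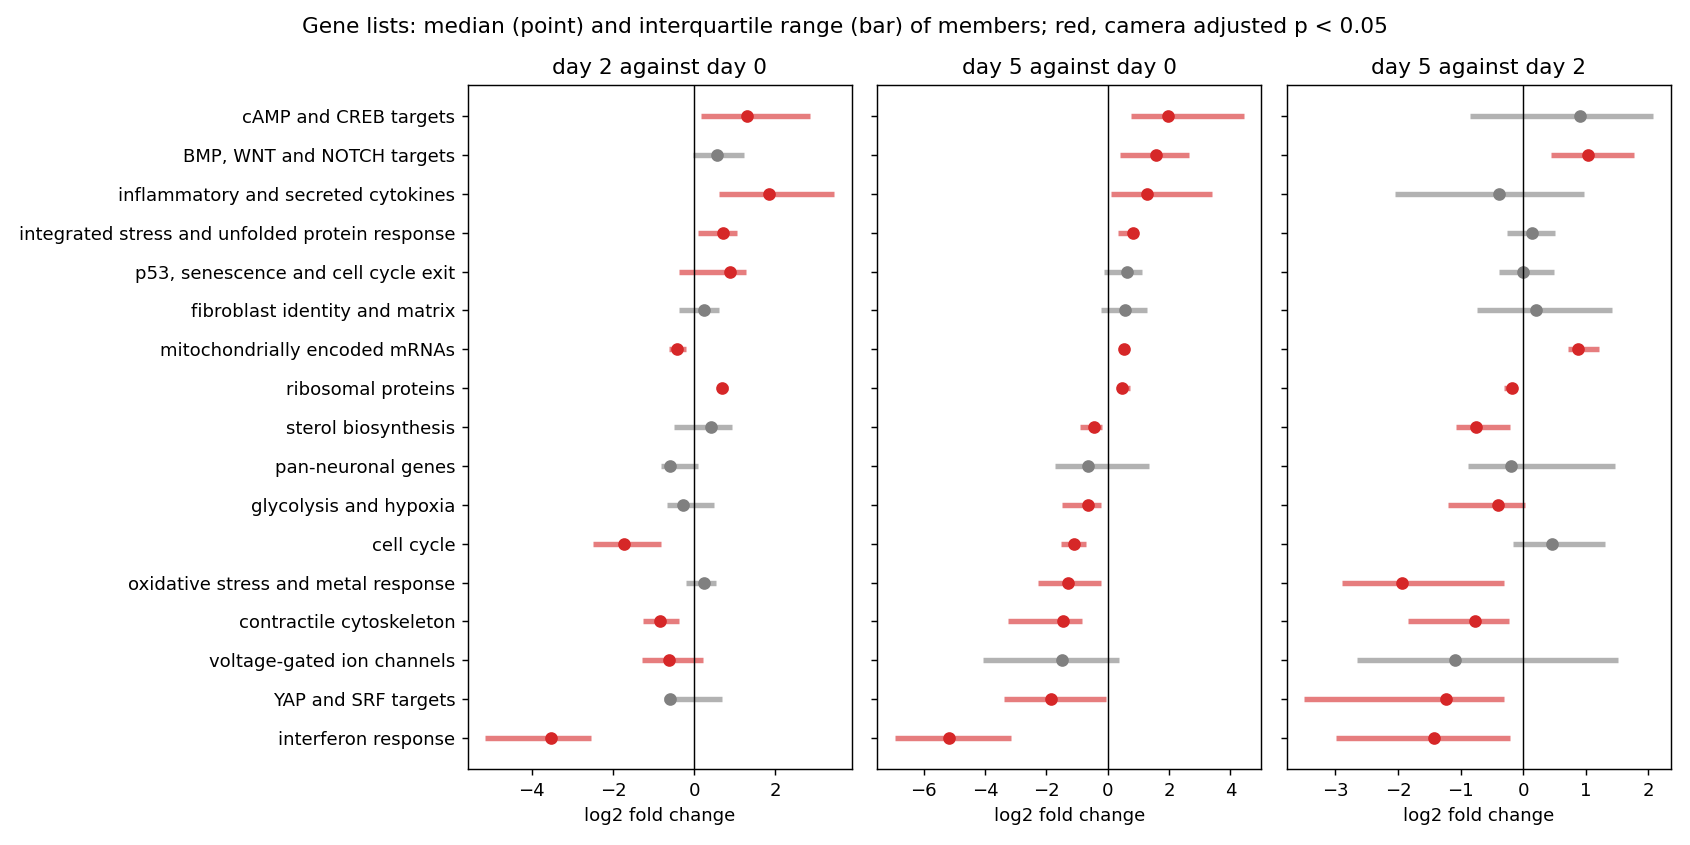
Median log2 fold change (point) and interquartile range (bar) of the tested members of 17 fixed gene lists (y axis) on a log2 x axis, with 1 panel per comparison and red for lists with a camera adjusted p under 0.05. Interferon-stimulated genes lay at -3.53 at day 2 and -5.19 at day 5 against day 0, and cAMP and CREB targets at 1.30 and 1.97.

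Day 5 was compared with day 2 to find what changed during the time in maturation medium, with forskolin present throughout. Cells kept in induction medium to day 5 were not analysed here, so medium, time and length of forskolin exposure changed together. COL1A1 came back from 1076 to 3725 CPM (log2 fold change 1.79 ± 0.02), and MKI67 rose from 0.623 ± 0.355 to 6.29 ± 0.754 CPM, a 10.2-fold change (edgeR adjusted p = 5.5e-09). Of genes higher at day 2, PTGS2 went from 649 to 81.2 CPM and IL24 from 118 ± 1.47 to 2.17 ± 0.0636 CPM. VIM, TAGLN, TUBB3 (log2 fold change -0.68 ± 0.04, edgeR adjusted p = 8.0e-11) and MAP2 all fell between these days.

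Oxidative stress genes fell in 13 of 16 cases and rose in 1 (median -1.94, camera adjusted p = 9.6e-05, adjusted p = 0.184 with an estimated correlation). NQO1 was 14.6-fold lower (log2 fold change -3.87 ± 0.02, edgeR adjusted p = 8.3e-25), and the mitochondrial superoxide dismutase SOD2 went from 1842 to 213 CPM. Sterol synthesis genes fell in 18 of 23 cases and rose in 3 (median -0.76, camera adjusted p = 0.00094, adjusted p = 0.184 with an estimated correlation), with MSMO1 going from 113 to 26.5 CPM. Glycolysis and hypoxia genes fell in 17 of 24 cases and rose in 5 (median -0.41, camera adjusted p = 0.010, adjusted p = 0.266 with an estimated correlation), with GAPDH going from 4401 to 2524 CPM and HK2 at a log2 fold change of -2.60. Contractile genes fell in 14 of 18 cases and rose in 3 (median -0.78, camera adjusted p = 0.00082, adjusted p = 0.184 with an estimated correlation), and MYL9 went from 456 to 45.9 CPM. YAP and SRF targets fell in 12 of 16 cases and rose in 3 (4 adjusted over the list alone, median -1.24, or -0.83 with low-count members at their bound, camera adjusted p = 0.0060, adjusted p = 0.350 with an estimated correlation). Interferon-stimulated genes fell further in 13 of 22 cases and rose in 1 (median -1.43, or -1.38 with low-count members at their bound, camera adjusted p = 0.00082, adjusted p = 0.184 with an estimated correlation).

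Mitochondrially encoded mRNAs rose in 13 of 13 cases (median 0.88, camera adjusted p = 1.7e-05, adjusted p = 0.455 with an estimated correlation), and MT-ND2 went from 735 to 2095 CPM. BMP, WNT and NOTCH targets rose in 12 of 16 cases and fell in 2 (median 1.04, camera adjusted p = 0.0049, adjusted p = 0.220 with an estimated correlation). HEY1 rose by 5.03 ± 0.17 on the log2 scale and ID1 went from 65.7 to 147 CPM, while NKD2, an inhibitor of WNT signalling, had a log2 fold change of -3.75 ± 0.15. Ribosomal protein genes fell slightly in 29 of 36 cases and rose in 3 (median -0.18, camera adjusted p = 0.0012, adjusted p = 0.359 with an estimated correlation), with RPL7 at a log2 fold change of -0.52 ± 0.03.

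Other lists were mixed over the second interval. Of the cAMP and CREB targets 18 of 31 rose and 8 fell (camera adjusted p = 0.11), with NR4A1 up by 2.04 ± 0.05, CREM by 1.23 ± 0.08 and PDK4 at -2.38 ± 0.02 on the log2 scale. Of the cell cycle genes 19 of 39 rose and 6 fell (camera adjusted p = 0.12), and the kinesin KIF20A went from 1.64 to 5.95 CPM. Of the inflammatory genes 8 of 22 rose and 13 fell (camera adjusted p = 0.38). Fibroblast genes rose in 16 of 30 cases and fell in 13 (camera adjusted p = 0.38), among them the collagen chain COL3A1, from 2387 to 6441 CPM. Of the pan-neuronal genes 5 of 15 rose and 6 fell (camera adjusted p = 0.90), and STMN3, a stathmin of neurons, went from 7.64 to 26.2 CPM.

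Among the genes named by rule, which leaves out antisense genes, and with counts on both days, the largest fall over this interval was that of DEPP1. A target of FOXO factors on chromosome 10 at 44970981 to 44978810, DEPP1 went from 145 to 0.256 CPM, 551-fold lower. Falls of genes without counts at day 5 are known only as lower bounds. The NOTCH ligand DLL4 went from 119.7 to 0.739 CPM, the BMP antagonist GREM1 from 811 to 14.9 CPM and the serine protease inhibitor SERPINB2 from 478 to 6.34 CPM. Among the rises, APCDD1, a WNT inhibitor, had 1 count at day 2 and a ratio of 1384.5 with a counting interval of 248 to 54743. ABI3BP rose by 9.22 ± 0.11 on the log2 scale, SSTR2 by 8.86 ± 0.08 and SMOC1 by 8.38 ± 0.07.

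Gene annotation terms held in the deposited table were tested for the genes changed by more than 2-fold, a test added after the data were seen. At day 2 the higher genes were enriched for inflammatory response (46 of 234 genes, Fisher adjusted p = 2.2e-07) and cAMP phosphodiesterase activity (7 of 11, Fisher adjusted p = 0.00073), and the lower genes for type I interferon signalling (24 of 51, Fisher adjusted p = 1.8e-13). At day 5 against day 0 the higher genes were enriched for extracellular matrix (64 of 197, Fisher adjusted p = 8.3e-16) and the lower genes for type I interferon signalling (31 of 51, Fisher adjusted p = 1.1e-14) and actin binding (74 of 327, Fisher adjusted p = 6.0e-08). Inflammatory response was enriched there among both the higher (46 of 234, Fisher adjusted p = 0.00023) and the lower genes (55 of 234, Fisher adjusted p = 2.3e-06). Between day 2 and day 5 the higher genes were enriched for extracellular matrix (49 of 197, Fisher adjusted p = 2.8e-13), homophilic adhesion (30 of 119, Fisher adjusted p = 5.2e-08) and nervous system development (55 of 385, Fisher adjusted p = 7.9e-06). The lower genes of that interval were enriched for cell adhesion (80 of 441, Fisher adjusted p = 1.2e-08), ion channel activity (28 of 83, Fisher adjusted p = 3.1e-08) and collagen-containing extracellular matrix (54 of 280, Fisher adjusted p = 1.1e-06), so matrix and adhesion terms appeared in both directions. With all called genes, the planned test, 47 terms were called for higher and 85 for lower genes at day 2, 46 and 357 at day 5 against day 0, and 28 and 424 at day 5 against day 2. The leading terms were cotranslational targeting to membranes for higher genes at day 2 (77 of 88, Fisher adjusted p = 1.0e-21), neutrophil degranulation for lower genes at day 5 against day 0 (227 of 375, Fisher adjusted p = 7.5e-20) and focal adhesion for lower genes at day 5 against day 2 (245 of 411, Fisher adjusted p = 3.1e-21).

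Across the time course, more genes were called in opposite directions over the intervals than in the same direction. Genes that rose to day 2 and fell to day 5 numbered 2831, against 1840 for independent calls, and those that fell and then rose 2409, against 1751. Genes that rose in both intervals numbered 1192, against 1752, and those that fell in both 1574, against 1839. Both intervals use the day 2 libraries, which by itself favours opposite directions, so the values for independent calls are too low a reference for turning back. Simulated unchanged groups gave at most 2 genes in any of these classes over 20 draws. With no change almost no gene is called, so those draws are no reference for the overlaps either. The covariance of the log2 fold changes of the intervals was -0.220, more negative than the -0.0395 of the simulations. Their correlation was -0.136, against -0.467 in the simulations. With no change the shared libraries alone set the correlation, while real changes add variance, so the correlations cannot be compared. Against day 0, 3389 genes were higher on both later days (1952 for independent calls) and 3466 lower on both (1860). The covariance of these comparisons was 1.14, against 0.0410 in the simulations, and their correlation 0.578, against 0.481. The spread between replicate libraries, as simulated, thus gave little of this covariance. A trait common to both day 0 libraries would not show in the simulations, and splitting these libraries would leave 1 on each side. To that extent, part of the excess in shared calls may still come from the shared controls.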

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

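The tests of technical explanations given here were chosen after the results were seen. For both gene list patterns, the test of scaling by the spread of the falls replaced counts of genes called lower under RLE factors, under library totals and without IGFBP5 (at least 8 and 22). These settings lowered the median gene, so those counts had little room to drop and were set aside.

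Of the 172 loci without a gene name, which entered no comparison, 6 at day 2 and 13 at day 5 reached at least 1 CPM in both libraries of the day and more than 2 times the highest day 0 library. The effect of day against day 0 turned round between day 2 and day 5 for part of the genes. In all, 971 genes were higher at day 2 and lower at day 5 than at day 0, against 1860 for independent calls. Another 757 were lower and then higher, against 1951. Both comparisons share the day 0 libraries, which favours calls in the same direction, so the values for independent calls are no fair reference. For all of these genes each change, and the difference between the days, was called by edgeR. The call of the difference adds little, since opposite changes against the same libraries nearly ensure it. By glmTreat at 2-fold both ways, 44 genes rose and then fell below day 0, and 15 did the opposite. DEPP1 had log2 fold changes of 4.12 and -4.99 against day 0, and the purine receptor P2RY1 2.46 and -3.67. The adhesion molecules TENM4 (-4.45 and 3.84) and PCDH7 (-3.40 and 1.81) went the other way. PCDH7 was picked from these genes after its values were seen.

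Pan-neuronal genes went both ways at day 5 against day 0, with 8 of the 15 tested lower and 5 higher, or 6 lower and 4 higher by more than 2-fold with glmTreat. The list had a median log2 fold change of -0.63, a mean of 0.13 and no call (camera adjusted p = 0.39), and the explanations weighed concern the 8 that fell. Scaling, with IGFBP5 taking 10.7% of the day 5 counts, could lower other genes, but it would move all of them alike. The interquartile range of these 8 falls was 1.39 log2, against a median SE of 0.11. Most tested genes changed, so such a spread would arise with or without a shift in scale and decides nothing. The median of the 8 falls was -1.70, which is negative by selection, since these genes were taken as called lower. Relative to TMM, RLE factors moved the median gene by -0.03 log2 and library totals by -0.21. Both shifts were downward and could only deepen the falls, so they cannot test whether scaling made them. They show only that the choice among these scalings moves genes by much less than the size of these falls. The depth limit of the shallower day 5 library, 0.180 CPM for 3 counts, bears on undetected proneural factors and not on these falls, so it decides nothing about them. The time in the protocol, the factor that the groups differ by, stays open as the biological explanation and was not tested further.

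Interferon-stimulated genes fell in 22 of 22 cases by day 5. Their median log2 fold change was -5.19, against 0.04 for all tested genes. Their interquartile range was 3.77 log2, against a median SE of 0.13, a spread that would arise with or without a shift in scale. Relative to TMM, RLE factors moved the median gene by -0.03 log2 and library totals by -0.21. Shifts of that size argue against the choice among these scalings as the whole cause. Leukocytes lost from the day 0 cells could bring such transcripts, but the summed level of leukocyte markers at day 0 was at most 2.82 CPM, nearly all of it CORO1A, against 496 CPM for MX1 alone, which argues against them. Medium and time may account for the fall as well as forskolin does, and 0 libraries in changed medium without forskolin were analysed, so these explanations cannot be told apart.

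Between 65.8% and 69.9% of tested genes were called in each comparison. At least 11314 genes were called at day 5 against day 0 under RLE factors, under library totals and without IGFBP5. A change of scale moves calls from higher to lower with little change in their total. The total therefore cannot decide whether scaling added calls. Replicates that share a culture or an RNA could give too small a spread and so too many calls. Squared differences of replicate libraries were on average up to 4.80 times the counting variance in the class of genes with the highest counts. They were 2.14 to 2.20 times that variance in the middle class and 2.28 to 2.49 times in the lowest. These values leave open both a shared and a separate culture.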

How the results depend on the processing

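The settings with library totals, without IGFBP5, with terms from glmTreat calls and with an assumed variation of at least 20% were chosen after seeing the data. Counts of called genes stayed within 1.5 times under DESeq2, limma-voom, RLE factors, library totals, without IGFBP5, without a filter, with a stricter filter, with only the compared groups and with each library left out. They moved under glmTreat (1141 higher and 904 lower at day 2 against day 0, 1591 and 1687 at day 5 against day 0, 1046 and 1299 at day 5 against day 2), which asks for a change above 2-fold. They also moved when a variation of at least 20% was assumed in every gene (2812 and 2473, 3414 and 3173, 2631 and 2819), which raises the assumed spread. Leaving out 1 library at a time gave 4935 to 4995 higher and 4810 to 4998 lower genes at day 2 against day 0, 5217 to 5279 and 5039 to 5239 at day 5 against day 0, and 4663 to 4733 and 5081 to 5174 at day 5 against day 2, with 9 to 10, 13 to 14 and 9 called lists. The library left alone in its day was assumed to vary like the others. Camera with an estimated correlation, at 3 degrees of freedom, called 0 lists in each comparison, with 7, 9 and 5 lists at an unadjusted p under 0.05. The estimate lay below the preset 0.01 for the interferon (0.0045), cell cycle (0.0056), contractile (-0.00023) and cAMP lists (-0.012). Those values argue against gene correlation as the reason that these lists lost their calls. Among called lists it lay above 0.01 for mitochondrial mRNAs (0.881), ribosomal proteins (0.104), YAP and SRF targets (0.064) and voltage-gated channels (0.015). The set test fry called 27, 26 and 27. Of the lists called, only the voltage-gated channels at day 2 also lost their call under other settings. Beyond fry, calls were gained by the neurotransmitter receptors at day 2 (library totals, and without day 2 replicate 2) and by the channels and axon guidance genes at day 5 against day 0. Terms moved with DESeq2 calls at day 2 (93 for higher and 136 for lower genes) and with glmTreat calls (50 for lower genes at day 2, 182 and 211 at day 5 against day 0, 117 and 195 at day 5 against day 2), of which 17, 18 and 105, and 12 and 98 were shared with the planned test. For higher genes at day 2 the count with glmTreat calls stayed at 47, but 9 of these terms were shared. The cause was not tested. Of 226 values of named genes, 225 kept their direction and side of the threshold under DESeq2 and under RLE factors, and 223 under library totals, where 2 lost their call and VIM at day 2 was reversed, to -0.13, by the shift in scale. With a library left out, calls were lost for CREM, SOX11 and DLX1 at day 2 and for no other named gene. The replicate numbers did not pair the libraries, with correlations of same-numbered deviations of 0.00269, -0.00241 and -0.00503. With the replicate number as a block, 5408 genes were higher and 5398 lower at day 2 against day 0, 5737 and 5560 at day 5 against day 0, and 5156 and 5486 at day 5 against day 2, with 10, 14 and 9 lists called, and all 226 named values kept their call. Counts of genes shared between comparisons were rerun only with DESeq2, RLE factors and the replicate block, and stayed within 1.5 times. Depth limits what can be said of genes near 0.180 CPM.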

Other observations

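The test of REST was chosen after its result was seen, and the decidual list was written before its result was seen but after other values of these libraries were known, including 3 of its 21 genes in the fixed lists.

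Some genes outside the rule, picked after their values were seen, also rose by day 5. IGFBP3 went from 58.8 CPM at day 0 and 128 CPM at day 2 to 19603 CPM at day 5, and the type I collagen chain COL1A2 went from 5053 to 14326 CPM while COL1A1 did not rise. PRRX1, a homeobox factor of limb and skin mesenchyme, went from 7.07 to 132 CPM (log2 fold change 4.21 ± 0.08), and TWIST1 rose by 2.07 ± 0.12. The NOTCH target HES1 had 1 count at day 0 and a ratio of 271 at day 5, with a counting interval of 48.0 to 10755.

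Members of uncalled lists also changed a lot, and these too were picked after their values were seen. The calcium channel gene CACNA1C went from 20.6 to 169 CPM at day 5, while SCN9A went from 68.0 to 1.32 CPM. The GABA receptor subunit GABRA2 went from 8.45 to 57.0 CPM at day 2 and to 3.88 CPM at day 5. The guidance receptors NRP1, NRP2 and ROBO1 had log2 fold changes of 1.96, 2.12 and 1.78 at day 5, and EPHB2 one of -3.20. The receptor KDR went from 4.16 to 61.8 CPM. The vesicle fusion gene SNAP25 went from 5.89 to 18.3 CPM, and the adhesion molecule L1CAM, with 2 counts at day 5, was lower by a ratio of 132 with a counting interval of 36.2 to 1092.

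Raised cAMP is used to decidualise endometrial stromal cells in culture, so a hypothesis is that a decidual stroma programme rose in these fibroblasts. The test asked for more members called higher than not, and a median above 1. Of 21 such genes 17 were tested, 11 rose and 4 fell at day 5 against day 0, with a median of 1.48, which meets this and is consistent with the hypothesis. Camera did not call the list against other genes (unadjusted p = 0.0624, and p = 0.138 with an estimated correlation). TIMP3 went from 272 to 4425 and 6223 CPM and SGK1 from 25.8 to 218 CPM, and IGFBP1, FOXO1, HAND2 and WNT4 rose to 5.44, 0.755, 0.532 and 2.71 CPM, but BMP2, DKK1, CRYAB and CEBPD fell, and PRL had 0, 4 and 9 counts over the libraries of day 0, 2 and 5, too few to test. Some of these genes may respond to cAMP in fibroblasts without any such programme, which was not tested.

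A second hypothesis was that loss of REST, a repressor of neuronal genes, could account for the synaptic and secretory genes that rose. REST did not fall at day 5 (log2 fold change 0.11 ± 0.07, edgeR adjusted p = 0.178), which argues against lower REST mRNA as the cause. Of 18 REST targets, 15 of them also in the fixed lists, 12 were tested, 6 rose and 4 fell, with a median of 0.32 (camera unadjusted p = 0.850). The value that decides this test was changed from the targets' median to the level of REST after the first output had been seen.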
